A study of Homo sapiens with 22 samples.

How the data were processed

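Blood was collected into tubes that stabilise RNA, and, per the labels' protocols, total RNA was treated with DNase, depleted of globin and ribosomal RNA and made into strand-specific libraries. The 11 patients gave 2 samples each, and the title of each sample names its patient and draw. The submitters' processing notes name GRCh37 and DESeq2; the aligner, the counting program, the gene annotation and the use of strand in counting are not given in the sources used here. The reference at hand was of another build, so no coordinates are printed.

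The deposited table lists 16640 genes. Its expression values are RPKM, reads scaled by gene length and by the library's total, computed by the authors for each sample. The group means in the deposited table are a signal, which the file headers name only as base means. That they are mean counts scaled by size factors was worked out from the recovery of reads described below. The authors also deposited the fold change as a ratio, its log2 value, and a p-value with an adjusted p-value, all second over first draw. These adjusted p-values equal a Benjamini-Hochberg adjustment over the listed genes. Genes with low mean values are absent from the table, whose lowest mean is 4.49 scaled reads. Mitochondrially encoded transcripts are not analysed here.

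Whole reads were recovered from the RPKM values and the authors' group means. Of 366080 values, 366080 came within 1e-06 of a whole read, and on simulated values 100.0% of reads were recovered exactly. The recovered libraries held 14727708 to 24728222 reads (median 18430424), which sets the precision of low genes. A count-based test had been chosen before the data were examined; because the deposited unit is RPKM, limma on log2(RPKM + 1) took its place. A fold change on the log2(RPKM + 1) scale understates the change of low genes.

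Genes needed an RPKM of at least 1 in at least 11 samples, which left 12285 genes. limma 3.58.1 in R 4.3.3 was fitted with the patient as a block and a trended prior variance, with Benjamini-Hochberg adjustment at 0.05. Tested on data simulated for the second against the first draw over 12285 genes, this fit recovered 90 of 100 genes changed by 2-fold and 99 of 100 changed by 4-fold, and called 13 unchanged genes. The simulated genes varied independently of each other, whereas real genes moved together (estimated correlation 0.81 in the platelet list). These shares therefore do not show which changes the real comparison could have missed. The same-patient pairing comes from the labels. Deviations of both draws of a patient from their group means correlated at 0.12 to 0.58 (median 0.36), against a median of -0.04 between patients. Of the 11 second draws, 7 correlated best with their own first draw, and 8 of 11 first draws with their own second. The remaining draws correlated better with a draw of another patient. No pair of libraries agreed within sampling noise. The fold changes in the authors' deposited table lay closer to a negative binomial regression with a patient term (median absolute log2 difference 0.012 over 500 genes) than without one (0.029).

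The 34 gene lists were fixed before the data were examined, and 31 had at least 5 tested genes. They were tested with camera, 2-sided, at a preset correlation of 0.01. The alternatives were camera with an estimated correlation, fry, and exact sign flips of each list's mean change over 2048 patterns, for which the smallest p possible is 0.00098. In camera a list is set against the other genes, while in fry and the sign flips it is set against no change. Their counts therefore answer different questions. The gene-level alternatives were median-of-ratios scaling, limma-voom on the recovered reads, a pseudocount of 0.1, no filter, another filter, no block, other thresholds, totals without globin and ribosomal RNA genes, and leaving out each patient. Swaps of the draws within patients gave 100 splits, the true order included.

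Genes were named by a rule fixed before the data were examined. Its first part takes genes with an adjusted p under 0.05, a mean log2 CPM of at least 0 and the same direction in at least 9 of 11 pairs, and of these the 10 with the largest rise and the 10 with the largest fall, leaving out sex-linked marker genes, immune receptor segments, HLA genes and unnamed clone-based loci. Its second part takes up to 4 members with the smallest p of each described list, and its last part a set of 12 genes in any case. No gene met the first part in the limma fit, so it was applied to the authors' deposited table instead, a choice made after the limma result was seen. In a first run, entries with LINC, MIR, KIAA or open reading frame symbols were also left out, which is wider than the rule. The reading was narrowed to the fixed wording after the names had been seen, and LINC01093 and MIR3605 replaced CDK5R1 and DGKH, with 18 of 20 names shared.

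Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the recovery of reads, correlations and figures, with 100000 permutations for each correlation.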

Results

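Whole blood was taken from 11 patients with intracerebral haemorrhage, bleeding into the brain tissue, and its RNA was sequenced after depletion of globin and ribosomal RNA. Each patient gave a first sample within 24 h of the onset of symptoms or of last being known well, and a second sample 72 h ± 6 h after the first. The 22 libraries form 2 groups of 11, and the question of the study is which transcripts differ between the draws of the same patient. The libraries held between 14727708 and 24728222 reads in the listed genes, with a mean of 18795811 ± 2274009 (SD, n = 11) at the first draw and 18928253 ± 3373834 (SD, n = 11) at the second. No healthy or untreated blood was part of the comparison, so values at the second draw are set only against the first.

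At the second draw, the mean transcript lists of eosinophils, granule-making immature granulocytes, platelets and non-classical monocytes lay above the first draw in most patients. Of these groups, the granulocyte list changed little (-0.16 to 0.25) in several patients. None of these groups passed a list test with an estimated correlation (adjusted p = 0.17 for the granulocyte, platelet and non-classical monocyte lists), the eosinophil list had too few tested genes for that test, and swapping draws within patients gave as many list calls in 29 of 100 splits. The authors' deposited table holds 126 higher and 24 lower genes at an adjusted p under 0.05, of which 43 and 10 differed by at least 2-fold. The clearest single gene was PI3 (gene 5266), which encodes elafin, an inhibitor of neutrophil elastase. Its RPKM was 19.0 ± 9.64 (SD, n = 11) at the first draw and 75.4 ± 40.3 (SD, n = 11) at the second, and it was higher in 10 of 11 pairs. In the limma fit with the patient as a block its log2 change was 1.89 with an SE of 0.29 and a Benjamini-Hochberg adjusted p of 0.12, which misses the threshold. PI3 did pass an adjusted p of 0.05 with limma-voom on the recovered reads, under both library sizes used. The authors' deposited table gives a log2 fold change of 1.95 with an adjusted p of 5.4e-10 for PI3.

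No gene passed an adjusted p of 0.05 in the limma fit of 12285 genes, with 0 higher and 0 lower. At an unadjusted p under 0.05 there were 693 higher and 411 lower genes, and 608 higher and 596 lower ones after median-of-ratios scaling. These counts were 361 and 202 with no replicate block, and the lower genes numbered 250 without the pair of replicate 11. With limma-voom on the reads recovered from the values, the counts were 1 higher gene (PI3) and 1 lower (COL9A2) with median-of-ratios library sizes. With total counts they were 1 higher (PI3) and 2 lower (COL9A2 and KLF9). Without the pair of replicate 6, limma called 92 genes higher and 27 lower. Of the 150 genes in the authors' deposited table, 116 were tested here, and all 116 had the same sign and an unadjusted limma p under 0.05. Of the 150, 140 moved the same way in at least 9 of 11 pairs and 15 in all 11. The 150 genes were called on these same libraries. Their shared sign, low unadjusted p and direction were thus largely fixed in advance and do not test the calls.

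**Figure D1:**
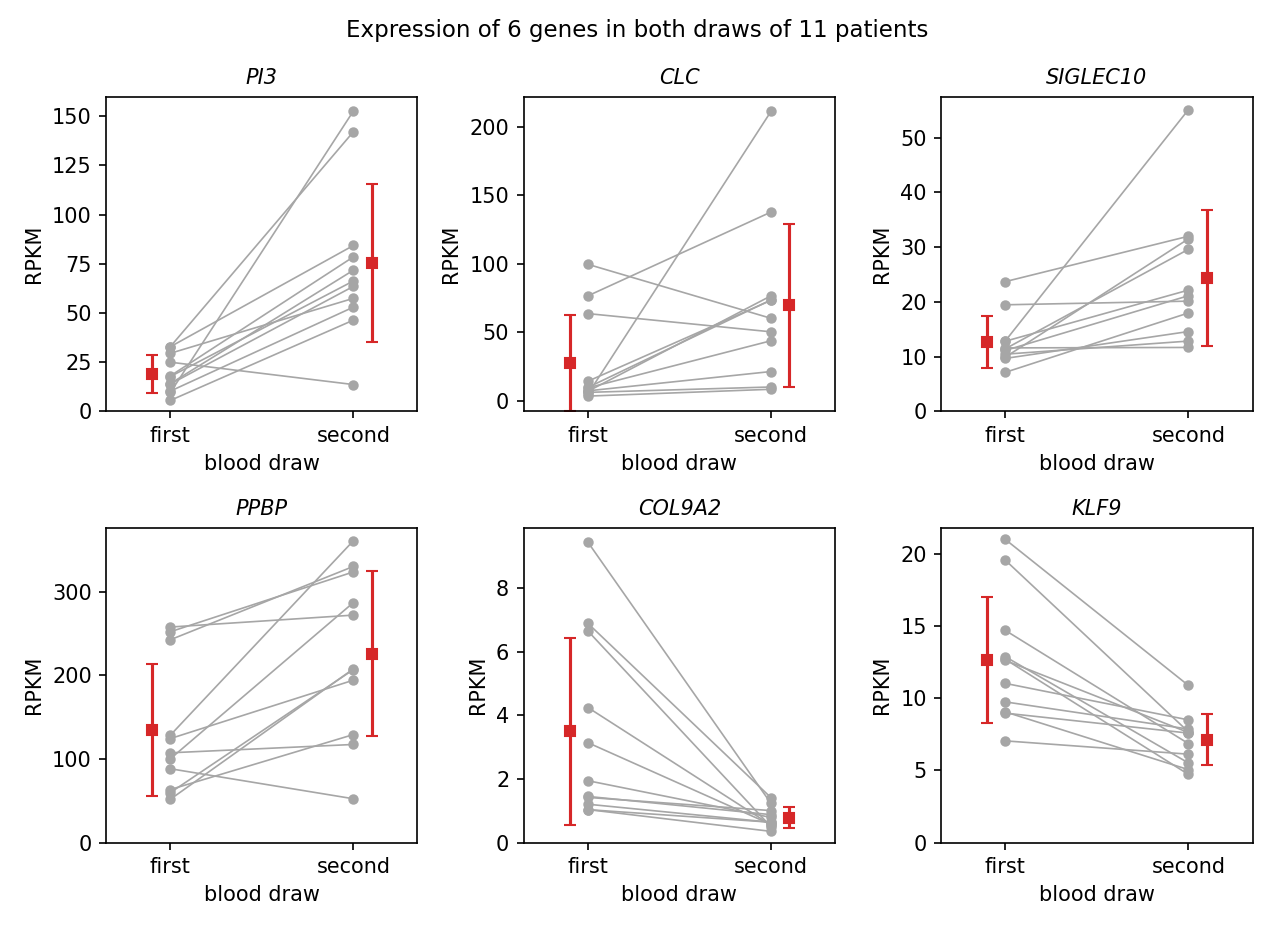
RPKM (vertical axes, linear) of 6 genes at the first and second draw; each grey line joins the draws of one patient, and red squares with bars are the mean ± SD of 11 patients. PI3 was higher at the second draw in 10 of 11 pairs, SIGLEC10 in 11 of 11, and COL9A2 and KLF9 were lower in 11 of 11.

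Among the 10 genes with the largest rise by the naming rule in the authors' deposited table, several are known from eosinophils and basophils. CLC, the Charcot-Leyden crystal protein of eosinophils, had an RPKM of 27.6 ± 34.7 (SD, n = 11) at the first draw and 69.8 ± 59.5 (SD, n = 11) at the second, and its log2 fold change in the authors' deposited table was 1.69 with an adjusted p of 0.0059. The eosinophil growth factor receptor chain IL5RA had a log2 fold change of 1.68 in the authors' deposited table, with an adjusted p of 0.0015. PTGDR2, a prostaglandin D receptor of eosinophils and basophils, had 1.88 there in the authors' deposited table, with an adjusted p of 0.018. DEFA4 and OLFM4, both carried in granulocyte granules, had log2 fold changes of 1.60 and 1.41 in the authors' deposited table, with adjusted p of 0.0015 and 0.0057. The remaining genes of this group were UGT2B11, TRHDE, TARM1 and SLC45A3, with log2 fold changes of 2.68, 1.71, 1.56 and 1.53 in the authors' deposited table. UGT2B11 has near-identical relatives, so its value is uncertain, and TRHDE, TARM1 and SLC45A3 lay under the RPKM filter of the limma fit.

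The largest falls included COL9A2, a collagen chain gene, whose RPKM was 3.50 ± 2.93 (SD, n = 11) at the first draw and 0.78 ± 0.33 (SD, n = 11) at the second, lower in 11 of 11 pairs. Its log2 fold change was -1.85 in the authors' deposited table with an adjusted p of 3.0e-06, and its limma log2 change was -1.10 with an adjusted p of 0.17. KLF9, a transcription factor induced by glucocorticoids, was also lower in 11 of 11 pairs, with an RPKM of 12.7 ± 4.36 (SD, n = 11) against 7.12 ± 1.76 (SD, n = 11) and a log2 fold change of -0.82 in the authors' deposited table (adjusted p of 0.00037). The interleukin 18 receptor chain IL18R1 had an RPKM of 81.7 ± 71.5 (SD, n = 11) at the first draw and 24.5 ± 7.25 (SD, n = 11) at the second, with a log2 fold change of -1.26 and an adjusted p of 0.022 in the authors' deposited table. CHI3L1, which encodes the secreted protein YKL-40, had -1.24 and GRAMD1C -1.26 in the authors' deposited table. LINC01093, EFNA1, MIR3605, EFHC2 and ITPKC complete the group, with log2 fold changes of -1.56, -1.17, -1.08, -0.85 and -0.75 in the authors' deposited table. Of these, LINC01093 and EFNA1 lay under the RPKM filter of the limma fit. The value of MIR3605, a short gene entry, is uncertain, since reads of an overlapping transcript could be counted in it.

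Of 31 gene lists tested with camera at a preset correlation of 0.01, 15 had an adjusted p under 0.05, 11 toward higher and 4 toward lower values at the second draw. This count does not separate the draws from chance: with the draws swapped within patients, 29 of 100 splits, the true order included, gave at least 15 lists. With an estimated correlation 0 lists passed, with fry 4 and with exact sign flips of the list means 0, so the lists below are given as values and directions. The fry calls were non-classical monocyte, residual globin, haem and iron handling, and coagulation and fibrinolysis, each with an adjusted p of 0.043.

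**Figure D2:**
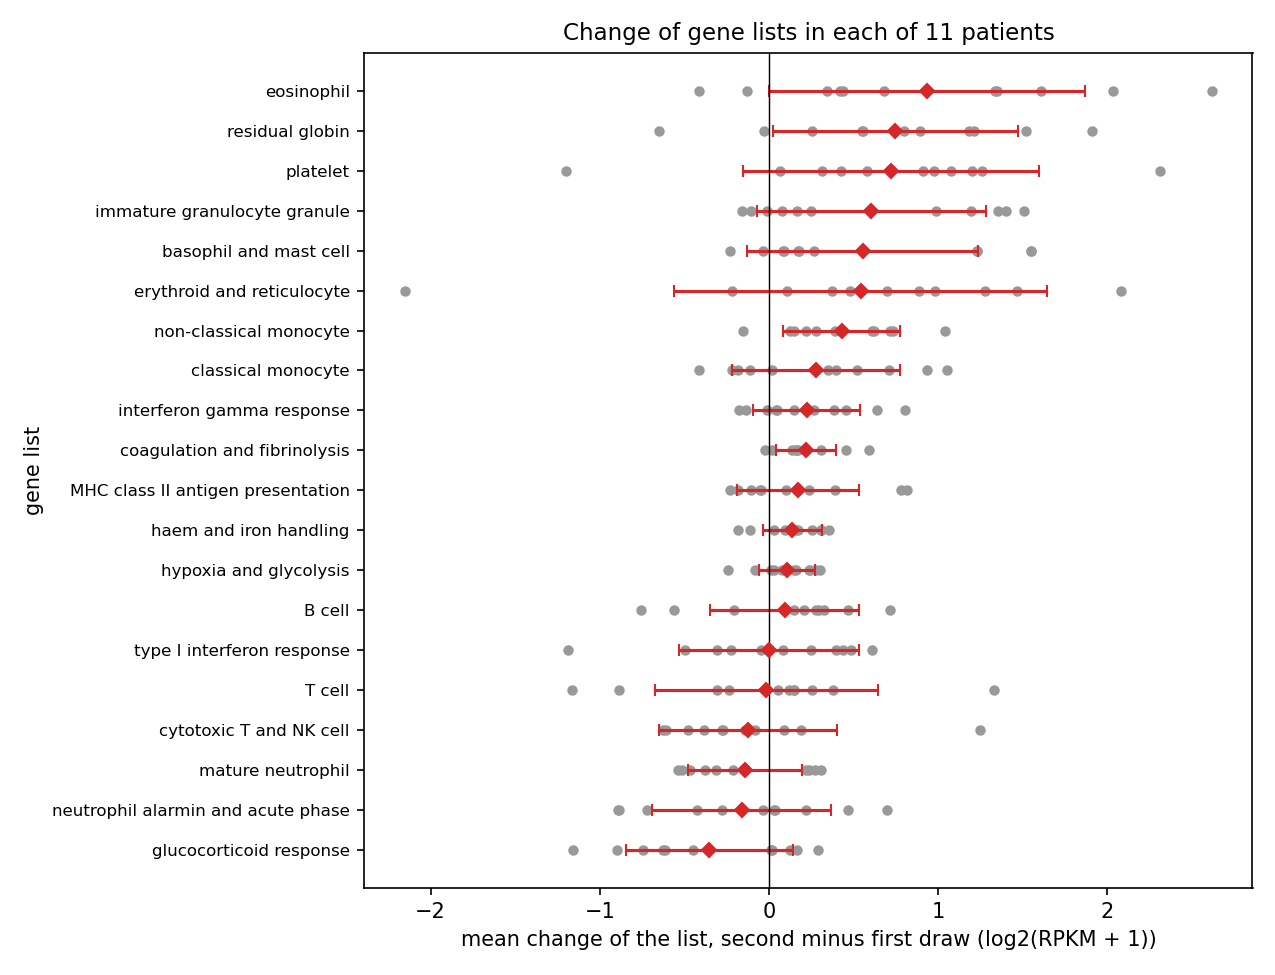
Mean change of each gene list in log2(RPKM + 1), second minus first draw (horizontal axis), for the lists past the preset camera threshold and 5 others; grey points are the 11 patients and red diamonds with bars the mean ± SD. The platelet list was above 0 in 10 of 11 patients and the glucocorticoid list in 5 of 11.

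**Figure D3:**
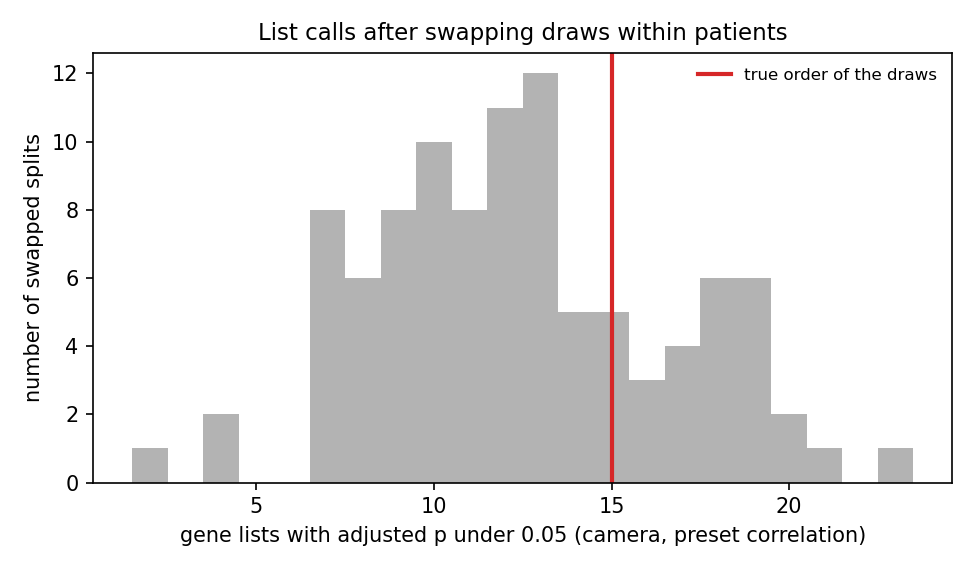
Number of gene lists with an adjusted p under 0.05 in camera with the preset correlation (horizontal axis) over splits made by swapping draws within patients; bars count splits and the red line is the true order. The true order gave 15 lists and the highest swapped split 23.

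List medians are over the tested member genes, while pairs are counted on the list mean. Among cell type lists, the immature granulocyte granule list had a median log2 change of 0.59 and was higher in 8 of 11 pairs. Its camera adjusted p was 4.5e-13, and 0.17 with an estimated correlation. In the pairs of replicates 3, 7, 8, 9 and 11 its mean changed by 0.99 to 1.51. In the other pairs it changed by -0.16 to 0.25. Of its 16 tested members, 0 passed over all genes, and 14 higher and 1 lower passed when adjusted over the list alone. BPI, LTF, DEFA4 and MMP8, all stored in neutrophil granules, had limma log2 changes of 0.58, 0.92, 1.31 and 1.12. The platelet list had a median of 0.69 and was higher in 10 of 11 pairs (adjusted p = 0.17 with an estimated correlation), and 14 of its 14 tested members were higher when adjusted over the list alone, against 0 over all genes. PPBP, a platelet chemokine, had an RPKM of 134 ± 78.9 (SD, n = 11) and then 225 ± 98.7 (SD, n = 11), and the integrin chains ITGB3 and ITGA2B had log2 changes of 1.22 and 1.04. The non-classical monocyte list had a median of 0.45 and was higher in 10 of 11 pairs (exact sign-flip p of 0.0039, adjusted 0.061; adjusted p = 0.17 with an estimated correlation), with 5 of 8 tested members higher when adjusted over the list alone. SIGLEC10, an inhibitory lectin, was higher in 11 of 11 pairs with a log2 change of 0.82, and the fractalkine receptor CX3CR1 had 0.59. The classical monocyte list had a median of 0.28 and was higher in 7 of 11 pairs (adjusted p = 0.43 with an estimated correlation), led by F13A1, CSF1R and MARCO with 0.87, 0.42 and 0.69.

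Red cell transcripts lay in the same direction, although globin RNA had been depleted. The residual globin list had a median log2 change of 0.86 and was higher in 9 of 11 pairs, with 6 of 7 members higher when adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). HBA2 and HBB had log2 changes of 0.90 and 0.86, and the near-identical copies HBA1 and HBA2 cannot be told apart with certainty. The erythroid and reticulocyte list had a median of 0.51 and was higher in 9 of 11 pairs, with 0 of 20 members passing when adjusted over the list alone (adjusted p = 0.43 with an estimated correlation). The pair of replicate 6 stood apart in the opposite direction, with changes of -2.15 in the erythroid, -1.20 in the platelet and -0.65 in the globin list, and without it the mean erythroid change was 0.81 against 0.54 with all pairs. ALAS2, the first enzyme of haem synthesis in red cell precursors, had a log2 change of 1.07. The eosinophil and basophil lists had too few tested genes for camera. All 4 tested eosinophil genes were higher, 3 of them when adjusted over the list alone, and the mean of the list was higher in 9 of 11 pairs (exact sign-flip p of 0.0078, unadjusted). Of the 3 tested basophil and mast cell genes, CPA3, a mast cell and basophil protease, was higher in 11 of 11 pairs with a log2 change of 0.71, and the list had an unadjusted exact sign-flip p of 0.015. These 2 lists were not part of the adjustment over the 31 camera-tested lists, in which smaller sign-flip p-values became 0.061.

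The glucocorticoid response list had a median log2 change of -0.38, with 1 higher and 4 lower members among 17 when adjusted over the list alone (camera adjusted p of 1.2e-08; adjusted p = 0.17 with an estimated correlation). Its mean was lower in 6 of 11 pairs and higher in 5. KLF9, ECHDC3 and IRS2 had log2 changes of -0.72, -0.75 and -0.54, while SGK1 had 0.26. The mature neutrophil list had a median of -0.12 and the neutrophil alarmin and acute phase list also -0.12, each with an adjusted p above 0.5 with an estimated correlation (0.51 and 0.62). In the alarmin list ORM1, an acute phase protein, had a log2 change of -1.34 and was the only member to pass when adjusted over the list alone. The cytotoxic T and NK cell list had a median of -0.10 (adjusted p = 0.66 with an estimated correlation), with 0 members passing when adjusted over the list alone.

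Among pathway lists toward higher values, coagulation and fibrinolysis had a median log2 change of 0.16 and was higher in 10 of 11 pairs (exact sign-flip p of 0.0029, adjusted 0.061; adjusted p = 0.17 with an estimated correlation). F13A1, PROS1 and SELP, which encode a clot-stabilising subunit, protein S and P-selectin, had 0.87, 0.60 and 0.62. SELP is also in the platelet list and F13A1 in the classical monocyte list, whose medians were 0.69 and 0.28. The haem and iron handling list had a median of 0.16 and was higher in 9 of 11 pairs (adjusted p = 0.17 with an estimated correlation), with BLVRB and FTL at 0.55 and 0.38 and the iron transporter SLC11A1 at -0.49. The interferon gamma response list had a median of 0.17 (adjusted p = 0.38 with an estimated correlation), and CD274, the ligand of the PD-1 receptor, had 0.83 and was its 1 member to pass when adjusted over the list alone. The MHC class II list had a median of 0.15 (adjusted p = 0.60 with an estimated correlation), led by IFI30 at 0.56. Its mean was higher in 6 pairs and lower in 5. The hypoxia and glycolysis list had a median of 0.14 (adjusted p = 0.43 with an estimated correlation), with VEGFA higher in 11 of 11 pairs at a log2 change of 0.21.

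The remaining 16 tested lists did not pass camera. The inflammasome and interleukin 1 family list had an adjusted p of 0.20 and held members of both directions. IL1B was higher in 11 of 11 pairs with a log2 change of 0.34, while IL18R1 had -1.22, and each passed when adjusted over the list alone. The NF-kappaB response list had an adjusted p of 0.14, and ICAM1, RELB and NFKB2 had log2 changes of 0.40, 0.41 and 0.38 and passed when adjusted over the list alone. The adjusted p of the other lists were 0.54 for T cell, 0.35 for B cell, 0.57 for plasmablast, 0.81 for dendritic cell, 0.82 for cytosolic ribosomal protein, 0.63 for Toll-like receptor signalling, 0.82 for type I interferon response, 0.84 for efferocytosis, 0.39 for complement, 0.78 for T cell checkpoint, 0.20 for mitotic cell cycle, 0.71 for autophagy, 0.82 for circadian clock and 0.25 for the ubiquitous leukocyte reference. The T cell, ribosomal protein and type I interferon lists had positive medians (0.02, 0.02 and 0.07) although camera placed them toward lower values, and the T cell checkpoint list had a median of -0.01 with camera toward higher values. The direction in camera is relative to the other genes, so it can differ from the sign of the median.

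Of the genes fixed for reporting in any case, 0 of 12 passed the limma test. IL1R2, ARG1, CD163 and FKBP5 had log2 changes of -0.53, -0.72, -0.51 and -0.48, and the first 3 of these had unadjusted p of 0.047, 0.029 and 0.046. MMP9, S100A12, CD177 and IFI44L had -0.26, 0.22, 0.37 and -0.32. HLA-DRA, CD3E, MS4A1 and HMOX1 had 0.15, 0.03, 0.14 and 0.03. All 12 had limma adjusted p of at least 0.477.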

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

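The limma-voom fit with total counts, the sign flips of list means, the unfiltered and 0.1-pseudocount list tests and the alternatives to the counts at an unadjusted p were added after the data were seen. The main counts were 0 genes higher, 0 lower and 15 lists. limma-voom on recovered reads called 1 higher gene (PI3) and 1 lower (COL9A2) with median-of-ratios library sizes. With total counts it called 1 higher (PI3) and 2 lower (COL9A2 and KLF9). Leaving out each patient gave 0 to 92 higher and 0 to 27 lower genes. Without replicate 6 there were 92 and 27. There was 1 higher gene without replicate 1 (PI3) and 1 without replicate 10 (P2RY14). Of the 119 genes called without replicate 6, 60 are among the 150 of the authors' deposited table; the cause was not tested. The fit with no replicate block gave 0 higher, 0 lower and 15 lists, so the block changed none of these counts. At an unadjusted p under 0.05 the 693 higher and 411 lower genes became 361 and 202 with no replicate block, and the lower ones 250 without replicate 11. The other gene-level alternatives gave 0 and 0. With an estimated correlation 0 lists passed, with fry 4 and with sign flips 0; leaving out each patient gave 13 to 17 lists. Of the lists, the interferon gamma, MHC class II, mature neutrophil, alarmin and hypoxia calls were lost in at least 1 of the 11 fits without a patient, the alarmin and hypoxia ones in 4 each. Median-of-ratios scaling gave 13 lists. Directions turned in 27 list values of 9 lists, none of which passed in the main test; 24 of these values did not pass under the alternative either. The turned values that passed were those of ribosomal protein (adjusted p 0.0306 without replicate 1 and 0.0122 without replicate 2, from 0.0122 to 0.709 over the fits without a patient) and type I interferon (0.0244 without replicate 6, from 0.0244 to 0.971); the cause was not tested. Of 558 list values under alternatives, 468 kept their side and direction, 55 lost and 8 gained the threshold. Of 2679 values of named genes, 14 changed sign and none of those passed a threshold. A further 30 values gained the threshold with their sign kept, among them PI3, COL9A2 and KLF9 with limma-voom on total counts. None could lose it, since no gene passed in the main fit. The planned edgeR quasi-likelihood F test, DESeq2 Wald test and other count-model tests over all genes were left out by choice, since the deposited unit is RPKM. They could have been run on the recovered reads, so how many genes they would call is unknown.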

Other observations

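Except for the swap counts of unadjusted genes and lists and the regression of the glucocorticoid list, the tests in this part were chosen after the results were seen. Changes of leukocyte lists differed in direction between patients. Over the 11 pairs, the change of the mature neutrophil list and that of the T cell list correlated at r = -0.74 (permutation p of 0.0034, adjusted 0.0054 over 2 relations) and rho = -0.85 (p of 0.0012, adjusted 0.0024), and r was -0.75 without the 2 pairs farthest from the median. This is consistent with shifts of cell shares that go opposite ways in different patients, although values are relative within a library, so that part of a negative relation can arise from a rise in one cell type alone.

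Swapping the draws within patients tests whether the counts can be told from chance. For lists past the threshold, 29 of 100 splits gave at least the 15 of the true order, and the highest other split gave 23, so chance cannot be excluded as the source of that count. For genes at an unadjusted p under 0.05, 11 of 100 splits gave at least 1104, with a median of 495 and a highest of 3160 in the others, so chance is not excluded there either. Structure among the patients is one possible explanation of the high split, and it was not tested. With 0 genes higher and 0 lower in the true order, all 100 splits necessarily gave as many in each direction, which decides nothing; the highest others were 2 and 1. The preset correlation of camera thus gave many calls on these data whichever draw came first. By exact sign flips 0 lists passed, with a lowest adjusted p of 0.061, so no single list call stands on that test.

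The first pattern is the higher platelet, erythroid, granulocyte granule and non-classical monocyte lists at the second draw. A lower share of neutrophils would raise all other cell types alike, but the mean changes of all 12 other cell type lists, none picked for its change, had an SD of 0.35 on the log2 scale and ranged from -0.12 (cytotoxic) to 0.94 (eosinophil), a spread beyond that of exact sign flips of the pairs (p of 0.0098). Low genes are compressed on this scale, and the eosinophil and basophil lists had 4 and 3 tested genes. Equal shifts of cell types therefore need not give equal list changes. The 12 lists also include the granule list, whose leading members are stored in neutrophil granules. The spread shows that the lists did not move alike. It cannot decide whether a lower neutrophil share was the whole cause, since unequal list changes can also follow from equal shifts. For globin, less complete depletion at the second draw cannot be told apart from more red cell RNA: globin and non-globin erythroid changes correlated at r = 0.77 (permutation p of 0.0054, adjusted 0.0054) and rho = 0.61 (p of 0.052, adjusted 0.052), but r fell to 0.28 without the 2 pairs farthest from the median, so the relation rests on those pairs. A release of young granulocytes and platelets after the bleed stays an untested hypothesis, and chance stays open.

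The second pattern is the lower glucocorticoid response list, with a mean change of -0.35 ± 0.49 (SD, 11 pairs). Regressed on the change of the mature neutrophil list, the change had a slope of 1.27 and left an intercept of -0.18 (exact joint sign-flip p of 0.063). An intercept this uncertain over 11 pairs neither excludes nor shows a lower neutrophil share as a cause. The fall was not shared by all patients: the list mean changed by -0.45 to -1.16 in 6 pairs and by 0.01 to 0.29 in 5. Without the 2 pairs with the largest falls the mean was -0.20 ± 0.40 (SD, 9 pairs, exact sign-flip p of 0.16). It kept 57.4% of its size, with 4 pairs lower and 5 higher and a median of 0.01. The 2 pairs were picked for their falls, which moves the mean and the p toward no change. Whether a few patients make the pattern is therefore not decided by leaving them out. A decline of stress hormones or of steroid treatment was not tested.

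The third pattern is 150 genes in the authors' deposited table against 0 in limma. The 140 genes with the same direction in at least 9 of 11 pairs cannot decide whether the calls rest on 1 or 2 patients. A given direction is expected in 3.27% of unchanged genes, but these genes were selected for their change in the same pairs. A count of directions also does not show how much of a change 1 patient supplies. The limma count itself depends on 1 patient, since without replicate 6 limma called 119 genes, 60 of them among the 150. The RPKM unit is argued against by limma-voom on recovered reads, which called only 3 of the 150. That fit kept the RPKM filter, so it covers only the 116 of these genes that passed it. How each test estimates the spread of a gene was not tested, and the authors' test was not rerun on swapped draws, so how many of the 150 chance would give is unknown.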
